A study of Rattus norvegicus with 8 samples.

How the data were processed

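The series holds 8 Agilent rat gene expression arrays, read in 1 colour (Cy3), of liver RNA from male Fisher 344 rats aged 18 weeks. Per the labels, 4 rats were controls and 4 had received furan at 8 mg per kg body weight by gavage on 5 days a week over 90 days and were killed 24 hours after the last dose. Each array holds RNA of a separate animal, as the design text counts 4 control and 4 treated rats. The vehicle given to the controls was not given in the sources used here. Groups were taken from the sample labels, and every array and every value column of the series table was assigned to a sample.

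Per the file headers and the processing notes, the authors scanned the arrays and extracted the spot signals with Agilent Feature Extraction 10.7. The deposited scanner files give for each of 62976 spots a background-subtracted processed signal in intensity units (arbitrary fluorescence intensity, not log transformed). The deposited series table holds the authors' normalised intensities, and its values equalled the processed signal of the scanner files scaled to a 75th percentile of 1000 on each array. The main results start from the processed signal of the scanner files.

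Of the 62976 spots, 58717 were not controls, and they carried 30367 probes. Spots that the scanner software had marked as non-uniform or as outliers were left out before the remaining spots of a probe were averaged, and 170 probes with no usable spot on at least 1 array were left out, which left 30197. No spot was saturated on any array. A gene symbol was available for 23792 probes, through the transcript identifier in the array annotation for 18828, through a current symbol for 2882, through a synonym for 399, and as the array annotation wrote it for 1683. The reference gene table served only for gene names. Probe coordinates are those of the array annotation, on the rn4 build. The other 6405 probes had no symbol and were kept as features of their own, counted but not named.

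The log2 processed signal was expressed relative to the 75th percentile of the non-control probes of its array, so every level below is a log2 value with that percentile at 0. A probe was tested where the scanner software called it well above background on all 4 arrays of at least 1 group. Of 20268 such probes, the brightest was kept for each gene, which gave 17677 features, 13988 of them with a gene name. Furan was compared with control by limma 3.58.1 (lmFit and eBayes, without trend) in R 4.3.3, with Benjamini-Hochberg adjustment over all 17677 features, and a gene was called at an adjusted p below 0.05. All tests were two-sided. Every adjusted p of a gene comes from limma's moderated test and every adjusted p of a gene list from limma's camera with a preset correlation of 0.01, unless another test is named. Fold bounds are given for genes well above background on all arrays of one group and on none of the other: each level of the group without signal was raised to at least the lowest level called well above background on its array, and the difference between the group means was then taken. Some signals not called lay above that floor, such as Camkmt with a control mean of -6.90. An "at least" value therefore holds only for this floor.

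Before the data were examined, 35 gene lists, the tests, the alternatives and the rule for naming genes were fixed. The lists were biliary and ductular, intestinal and mucin, stellate cells and matrix, macrophage, lymphocyte, MHC class II, neutrophil, mast cell, endothelial, erythroid, hepatocyte, pericentral, periportal, proliferation, p53 targets, apoptosis, DNA repair, NRF2 targets, drug-metabolising P450, male-biased liver, bile acid metabolism, cholesterol synthesis, fatty acid oxidation, lipogenesis, acute phase, cytokines and chemokines, unfolded protein response, heat shock, preneoplastic, chromatin modifiers, imprinted genes, circadian clock, iron metabolism, Notch signalling and oxidative phosphorylation. A list was tested where at least 5 members were, and p values were adjusted over the 35 lists. Some lists share members, so their results are not independent. Gstp1 and Akr1b8, for example, are NRF2 targets and preneoplastic genes, and Cyp2c11 and Cyp3a18 are in the P450 and male-biased lists. After the data were seen, 7 lists were added for the tests of single patterns: smooth muscle, adipose, enterocyte, enteroendocrine, pancreas acinar, mesothelium and female-biased liver.

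Named genes follow the fixed rule. Among called genes well above background on all 8 arrays whose furan values all lay on one side of the control values, the rule takes the 12 largest rises and the 12 largest falls. It takes the 4 largest bounds in each direction. For each list it takes up to 3 called members in the direction that more called members took and the largest called member of the other direction, or the member with the smallest p where none was called. Cyp2e1, Gstp1, Krt19, Mki67, Cdkn1a and Afp were named whatever their values. Of the genes the rule takes, 2 are not reported singly and are left out of the counts of named genes; they stay in every test and list.

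The alternatives fixed beforehand were normexp background correction of the raw signals (offset 50), quantile normalization, centring on the median, the authors' table, no filter on dim probes, a signal above background on all 8 arrays, the mean of all probes of a gene, the replicate number as a block, the slide as a block, a variance trend with robust moderation, array weights, leaving out each array in turn, an adjusted p below 0.01, a test against a 1.5-fold change (limma's treat), camera with an estimated correlation, and limma's fry. After the data were seen, 4 more were added: leaving out both arrays that were out of the scanner software's range for the spread of replicate spots, each slide alone, and keeping the spots marked as outliers. The arrays lie on 2 slides, and each slide holds 2 control and 2 furan arrays. The split of the 8 arrays into 4 and 4 was repeated for all 35 ways of forming it. Files were read and tables prepared in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

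The procedure was tested on simulated data with 4 samples per group, the tested probes' levels and 50 shifted genes per fold size. It recovered 24% of the genes shifted 1.5-fold, 60% at 2-fold, 82% at 4-fold and 96% at 8-fold. Of its calls, 13 were of genes that had not been shifted (9.03%), and 0 had the wrong direction. The shifted genes were a far smaller share of the 20268 simulated features than the 6033 called among 17677 in the data. The adjustment is stricter where few genes change, so these percentages do not give the recovery in the data. Both simulated lists shifted 1.5-fold were called, as was 1 of 20 lists without a shift. The simulated noise was independent between genes. These lists therefore do not show how many false calls to expect where members are correlated, as in the measured lists. The number of arrays limits the precision of every value.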

Results

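Liver RNA of 8 male Fisher 344 rats was measured, with 1 array for each animal: 4 controls and 4 rats given furan, a liver carcinogen of rodents, at 8 mg per kg body weight on 5 days a week over 90 days. The 75th percentile of the processed signal was 827, 975, 1057 and 983 intensity units on control arrays 1 to 4 and 1486, 1596, 1456 and 1256 on furan arrays 1 to 4. The share of spots well above background was 70.9%, 74.8%, 73.4% and 72.8% on the control arrays and 78.2%, 78.5%, 74.3% and 73.2% on the furan arrays, in the same order. The number of arrays limits the precision. Correlations between arrays, taken across genes, ran from 0.980 to 0.992 within the control group, from 0.979 to 0.993 within the furan group, and from 0.954 to 0.980 between them. The median coefficient of variation between replicate spots was 9.38% on control 2 and 12.8% on furan 1, both out of the scanner software's range, and between 4.20% and 7.57% on the other 6 arrays. Arrays 1 and 2 of both groups lay on slide 1, and arrays 3 and 4 of both groups on slide 2.

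The series addresses how far changes caused by furan in the rat liver persist, and its arrays compare treated with control livers 24 hours after the last dose. Livers of furan-treated rats had higher levels of cell cycle genes, of genes that respond to the oxidant-sensing factor NRF2 and of genes known from preneoplastic rat liver. Camera called these lists with the preset correlation but not with an estimated one (proliferation adjusted p = 0.321, NRF2 targets adjusted p = 0.214 and preneoplastic adjusted p = 0.615 with an estimated correlation). Lower levels were found for hepatocyte genes, drug-metabolising and male-biased enzymes and acute phase proteins, again called with the preset correlation but not with an estimated one (adjusted p = 0.512, 0.650, 0.512 and 0.450 with an estimated correlation), and the P450 call also ended with normexp and with fry. Gstp1, a glutathione transferase used as a marker of preneoplastic foci, rose from a mean level of -0.82 ± 1.16 to 3.92 ± 0.55 (SD, n = 4 each), a 26.7-fold change. Cyp2c11, the main male-specific P450 of rat liver, fell by 2.13 on the log2 scale. The proliferation list had a median log2 change of 2.28 (medians of single arrays between -0.28 and 0.26 in controls and between 1.73 and 2.64 in furan-treated livers).

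Of 17677 features tested, 3054 were higher and 2979 lower after furan (limma, adjusted p below 0.05), so that 50.6% of the called features were higher. At least 2-fold changes were called for 913 higher and 672 lower features. Among the 13988 named genes, 2231 rose and 2407 fell, 776 and 563 of them at least 2-fold. For 6489 features (36.7%) the 4 furan values lay on one side of the 4 control values, against 2.86% by chance. With control 2 and furan 1 left out, 2518 features were higher and 2317 lower. With the slide as a block the counts were 3039 and 2919. Each of the 6033 called features had the same sign on both slides. The calls come from these same arrays, and opposite signs on the slides widen the spread within groups and hinder a call. The shared sign is therefore no separate support. Of 2360 genes with more than 1 tested probe, 25 had probes called in opposite directions. With normexp background correction 2796 features were higher and 6007 lower (31.8% higher), and the median change of all features was -0.18, against -0.03 in the main result and -0.12 without a filter on dim probes.

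**Figure D1:**
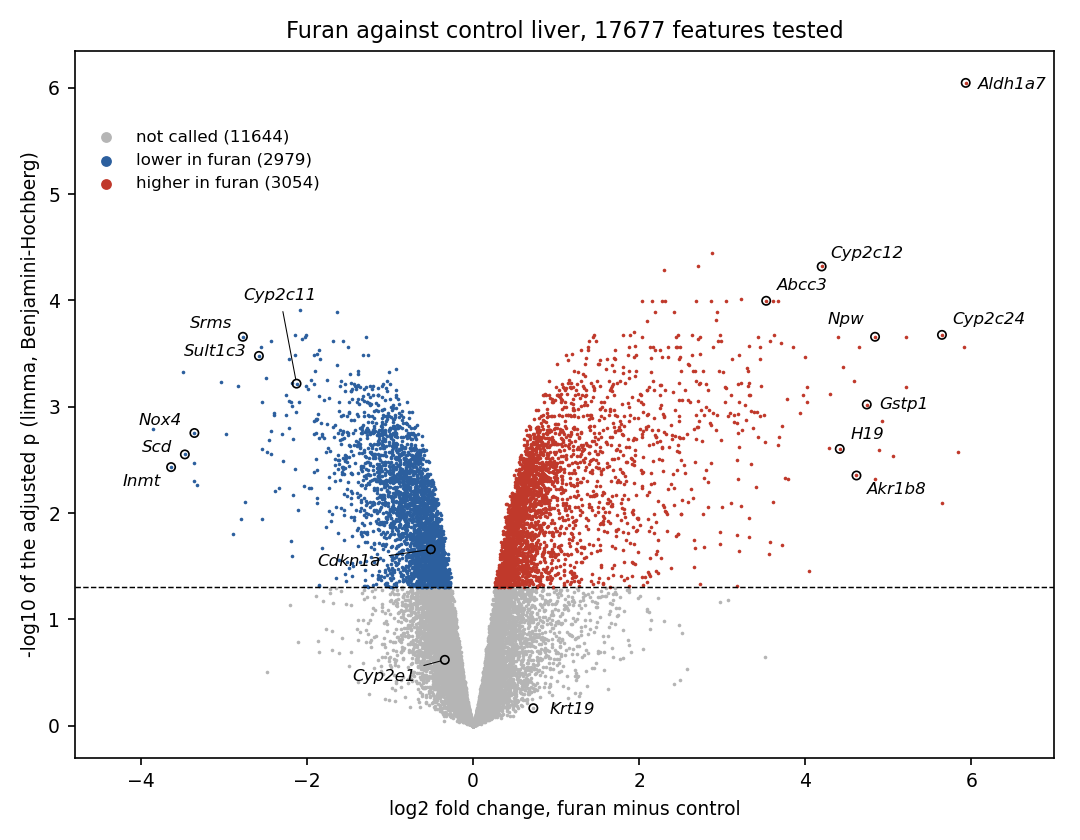
Log2 fold change (furan minus control, x axis) of the 17677 features against the negative log10 of limma's adjusted p (y axis), with the dashed line at an adjusted p of 0.05 and named genes labelled. Above the line lie 3054 features on the side of higher and 2979 on the side of lower levels in furan-treated livers.

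Among the 12 largest rises were Cyp2c24 with a log2 change of 5.65, Npw (neuropeptide W) with 4.84, Gstp1 with 4.74 and Akr1b8, an aldo-keto reductase, with 4.62. They also held Ddit4l (4.46), Acot1 (4.40), Ica1 (3.85), Ropn1 (3.78) and Nme4 (3.71). Among the largest falls were those of Inmt (-3.64), Scd (-3.47), Stac3 (-3.36), the NADPH oxidase Nox4 (-3.36) and Sez6 (-3.03). By the rule that chose them, the 4 values of one group lay apart from those of the other for each of them. With normexp the changes of Ddit4l (2.01), Ropn1 (1.57), Nme4 (2.30) and Nox4 (-2.12) were over 1.5 times smaller and still called. Features well above background on all furan and on no control array numbered 103, and 7 showed the opposite. The furan arrays were brighter, which lets dim probes pass the background mark more easily there. How far this made the imbalance was not tested, and not all of the 103 passed limma's threshold. Aldh1a7, an aldehyde dehydrogenase, was at least 50.6-fold higher (adjusted p = 8.98e-07), Slc5a9 at least 41.3-fold higher, and Doc2a at least 24.4-fold higher. Mmd2 was at least 9.27-fold lower and Chrdl1 at least 5.94-fold lower. These bounds depend on the floor, the lowest level called well above background, and a higher floor would give smaller folds. With normexp the log2 changes were smaller, 1.77 for Aldh1a7, 1.61 for Slc5a9, 1.28 for Doc2a, -1.11 for Mmd2 and -1.0 for Chrdl1, and these genes were called. Normexp itself lowers dim signals on the brighter furan arrays, so it gives no separate support for the falls. Nefm, at least 11.7-fold higher, had 0.60 with normexp and was not called there (adjusted p = 0.0837).

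The 27 tested NRF2 targets had a median log2 change of 1.06, with 19 higher, 1 lower and 7 not called, the same counts when adjusted over the list alone. The list was called (adjusted p = 6.72e-08, and adjusted p = 0.214 with an estimated correlation), with medians of 0.97 on slide 1 and 1.10 on slide 2. Gstp1 (log2 change 4.74 ± 0.55 SE, adjusted p = 0.000952, higher in 4 of 4 furan livers) has its probe on chromosome 1 (rn4 build) from 206628636 to 206628695 and rose by 5.55 on slide 1 and 3.94 on slide 2. Akr1b8 rose as well, and Aox1, an aldehyde oxidase, fell by 0.74. Gpx2, a glutathione peroxidase, rose by 3.72 on the log2 scale, while control 2, the array with high biliary markers, had a level of 2.16 against -2.42 to -1.92 in the other controls. The call of Gpx2 was lost without control 3 (adjusted p = 0.0534), control 4 (0.0527) or furan 2 (0.0582), in a range over all alternatives from 0.000884 to 0.225.

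Of 17 tested preneoplastic genes, 7 rose, 1 fell and 9 were not called (8 and 1 adjusted over the list alone). Gstp1 and Akr1b8 belong to this list and to the NRF2 targets. The list median was 0.57, called at an adjusted p = 0.0131, and adjusted p = 0.615 with an estimated correlation. Medians were 1.11 on slide 1 and 0.58 on slide 2, and 0.89 without control 2, 0.93 without furan 3 and 0.88 without furan 4. Array medians were -0.66, 0.93, -0.07 and -0.14 in controls 1 to 4 and 1.45, 1.21, 0.61 and 0.59 in furan livers 1 to 4, so control 2, the array with high biliary markers, was above furan 3 and 4. Afp (alpha-fetoprotein, chromosome 14 from 19092583 to 19092642) rose from 3.11 ± 0.06 to 4.46 ± 0.20 (SD, n = 4 each), a log2 change of 1.34 ± 0.12 SE with adjusted p = 0.000397. The imprinted transcript H19 rose 21.3-fold (log2 change 4.42 ± 0.67 SE), and Igf2, its neighbour in the imprinted domain, fell by 1.63 on the log2 scale.

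Of 34 tested proliferation genes, 30 rose, none fell and 4 were not called, and 33 rose when adjusted over the list alone. The list was called at an adjusted p = 1.94e-16, and adjusted p = 0.321 with an estimated correlation. Its median was 2.56 on slide 1 and 1.87 on slide 2, and 0.85 with normexp, where the list was still called (adjusted p = 7.74e-14; over all alternatives from 2.41e-24 to 0.321). Rrm2, a subunit of ribonucleotide reductase, rose by 3.42 on the log2 scale, with control 4 above the other controls (-1.19 against -3.37 to -3.01), and Ect2, a regulator of cytokinesis, by 3.32 (1.22 with normexp). Mki67 (chromosome 1 from 195310145 to 195310204) rose from -4.75 ± 0.26 to -2.28 ± 0.48 (SD, n = 4 each), a log2 change of 2.47 ± 0.25 SE with adjusted p = 0.000599. It rose by 3.01 on slide 1, by 1.94 on slide 2 and by 1.43 with normexp. The call of Aurkb, a mitotic kinase (log2 change 3.20), ended with normexp (0.27, adjusted p = 0.109, the highest of all alternatives, against 0.000747 as the lowest).

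DNA repair genes rose together in 14 of 22 tested members, with 2 lower and 6 not called, in the same numbers adjusted over the list alone. The median was 0.53 (adjusted p = 0.000342, and adjusted p = 0.214 with an estimated correlation), at 0.58 on slide 1, 0.47 on slide 2 and 0.35 with normexp. The polymerase subunit Pold1 rose by 1.18 and Xrcc5 by 1.00 on the log2 scale. Of 22 tested p53 targets, 9 rose, 2 fell and 11 were not called, and 10 rose and 2 fell when adjusted over the list alone. Their median of 0.46 was called (adjusted p = 0.0157, and adjusted p = 0.238 with an estimated correlation), with 0.44 on slide 1, 0.46 on slide 2 and 0.26 with normexp. The death receptor gene Fas rose by 1.26 (0.75 with normexp) and Zmat3 by 0.90. Eda2r, well above background on all furan and on no control array, was at least 2.56-fold higher. Its log2 change, 1.90 against control levels near background, was -0.28 with normexp. Cdkn1a, the cell cycle inhibitor p21 (chromosome 20 from 7385536 to 7385595), fell by 0.51 ± 0.14 SE from 2.86 ± 0.11 to 2.35 ± 0.23 (SD, n = 4 each, adjusted p = 0.0219), opposite to the list. Its other tested probe had a log2 change of 0.73, and the mean of both probes was 0.11. The call of Cdkn1a ended without control 1 (adjusted p = 0.0538), control 2 (0.0521), control 3 (0.0574) or furan 3 (0.050), in a range over all alternatives from 0.00691 to 0.689.

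**Figure D2:**
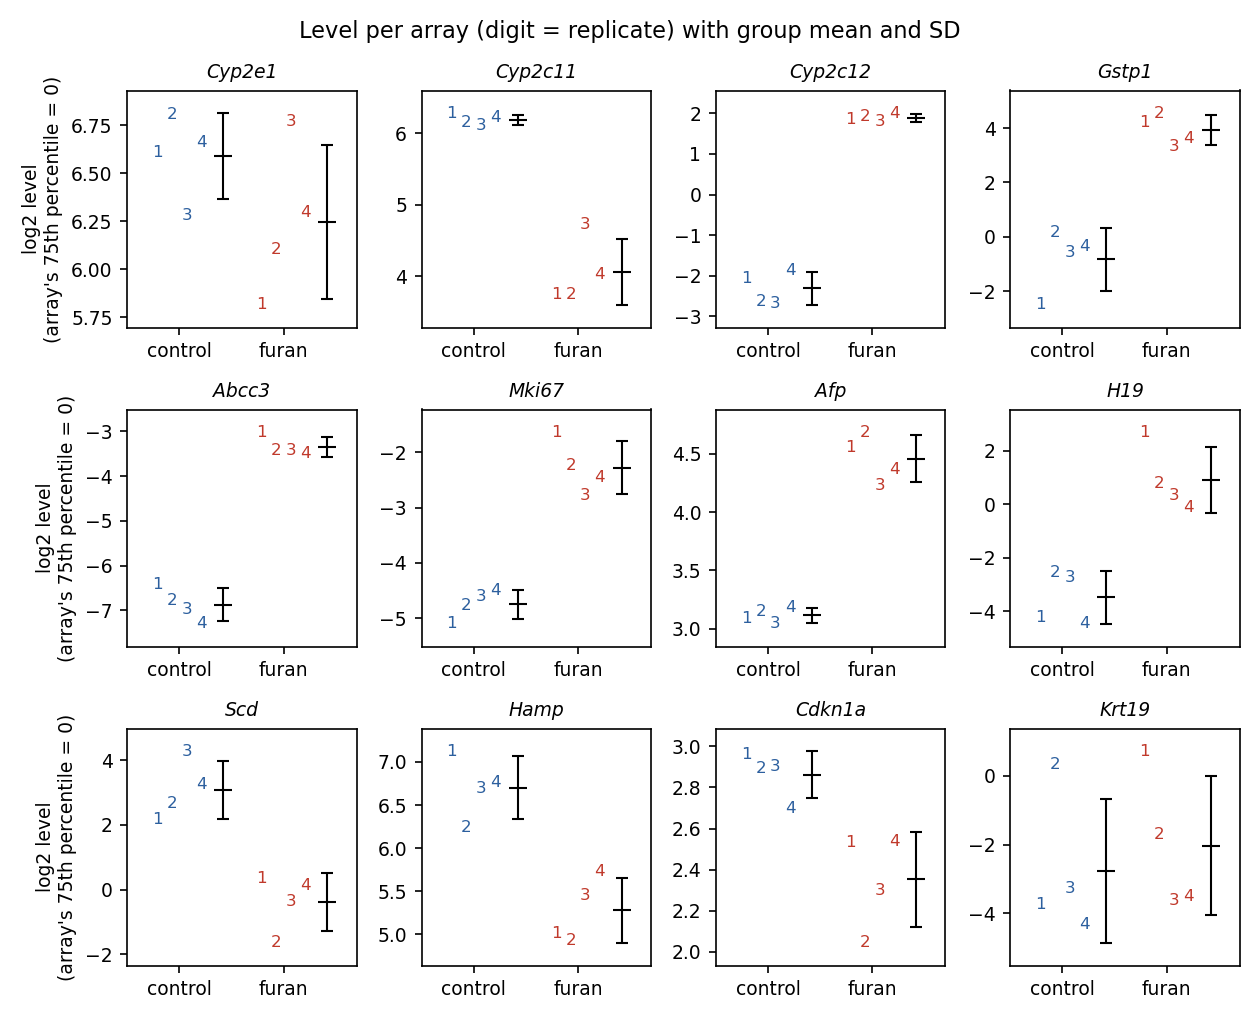
Levels of 12 named genes (y axis, log2 processed signal relative to the array's 75th percentile) on the 4 control and 4 furan arrays, with digits for the replicate and bars for the mean ± SD. Gstp1 has means of -0.82 and 3.92, whereas Krt19 is highest on control 2 (0.32) and furan 1 (0.71).

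Of 22 tested hepatocyte genes, 16 fell, 1 rose and 5 were not called (17 and 1 adjusted over the list alone). The median was -0.66 (adjusted p = 1.33e-05, and adjusted p = 0.512 with an estimated correlation), at -0.94 on slide 1 and -0.50 on slide 2. Clotting factor gene F9 fell by 1.57 and Pck1, an enzyme of gluconeogenesis, by 1.16 on the log2 scale. Apoa1, the main apolipoprotein of HDL, rose by 0.72 (1.14 with quantile normalization). Male-biased liver genes fell in 14 of 17 tested members, none rose and 3 were not called, in the same numbers adjusted over the list alone. Their median was -1.15 (adjusted p = 9.23e-06, and adjusted p = 0.512 with an estimated correlation), at -1.52 on slide 1 and -0.65 on slide 2. Cyp2c11 (chromosome 1 from 243320626 to 243320685) fell from 6.19 ± 0.07 to 4.06 ± 0.46 (SD, n = 4 each), by 2.46 on slide 1 and by 1.79 on slide 2 (adjusted p = 0.000606). Hsd3b5 fell by 1.75 and Cyp3a18 by 1.66.

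Of 30 tested drug-metabolising P450 genes, 18 fell, 4 rose and 8 were not called (19 and 4 adjusted over the list alone). The median of -0.85 was called (adjusted p = 0.00154, and adjusted p = 0.650 with an estimated correlation), with -1.20 on slide 1 and -0.50 on slide 2. The call ended with normexp (adjusted p = 0.0599) and with fry (adjusted p = 0.0900), in a range over all alternatives from 2.18e-06 to 0.650. Cyp3a23-3a1 fell by 2.29 and Cyp2c7 by 2.04 on the log2 scale. Against this direction, Cyp2c12, a female-specific P450 in adult rats, rose from -2.31 ± 0.40 to 1.89 ± 0.09 (SD, n = 4 each), an 18.3-fold change (log2 change 4.20 ± 0.19 SE, adjusted p = 4.79e-05), by 4.23 on slide 1 and 4.17 on slide 2. Its probe lies from 17424990 to 17425049 on sequence not assigned to a chromosome. Cyp2e1, the P450 that oxidises furan (chromosome 1 from 200927736 to 200927795), had levels of 6.59 ± 0.22 in controls and 6.25 ± 0.40 after furan. Its log2 change of -0.34 ± 0.21 SE was not called (adjusted p = 0.240, 95% interval from -0.82 to 0.14) and was -0.75 on slide 1 and 0.06 on slide 2. Neither zonal list was called: of 17 pericentral genes 2 rose and 6 fell (2 and 6 adjusted over the list alone, median -0.41, adjusted p = 0.109), and of 16 periportal genes 2 rose and 7 fell (2 and 9, median -0.57, adjusted p = 0.0563). Pericentral genes were called without furan 3 (adjusted p = 0.0477), on slide 1 alone (0.0409) and with fry (0.0304; over all alternatives up to 0.512). Periportal genes were called with the slide as a block (adjusted p = 0.0321), quantile normalization (0.0365), the mean of probes (0.0498), a variance trend (0.0416) and fry (0.0448), without control 2 (0.0409), furan 3 (0.0227) or furan 4 (0.0269), and on slide 1 alone (0.00371; over all alternatives from 0.00371 to 0.671). Apoa4 fell by 2.21 and Oat, an enzyme of the pericentral zone, by 2.13.

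Of 23 tested acute phase genes, 19 fell, none rose and 4 were not called, and 20 fell when adjusted over the list alone. The median of -0.94 was called (adjusted p = 6.72e-08, and adjusted p = 0.450 with an estimated correlation), at -1.07 on slide 1 and -0.86 on slide 2. Socs3, an inhibitor of cytokine signalling, fell by 1.48 (furan 2 at -4.17, the other furan arrays at -3.63 to -3.56), Hamp, the iron hormone hepcidin, by 1.42 and the pentraxin Apcs by 1.38. Of 21 tested genes of the unfolded protein response, 10 fell, 1 rose and 10 were not called (10 and 2 adjusted over the list alone). Their median of -0.50 was called (adjusted p = 0.00607, and adjusted p = 0.450 with an estimated correlation), with -0.56 on slide 1 and -0.39 on slide 2, but not with normexp (adjusted p = 0.136; over all alternatives from 0.00235 to 0.450). Sdf2l1 fell by 0.97, Creld2 by 0.87 and Dnajb9 by 0.80, all proteins of the endoplasmic reticulum. Cytokines and chemokines were not called as a list (22 tested, 1 rose and 5 fell, the same adjusted over the list alone, median -0.27, adjusted p = 0.114), except with fry (adjusted p = 0.0200) and on slide 2 alone (0.0142; over all alternatives up to 0.512). Within it Cxcl1, which attracts neutrophils, fell by 2.39 and Cxcl12 by 1.26.

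Of 16 tested lipogenesis genes, 6 fell, 2 rose and 8 were not called, the same adjusted over the list alone. Their median of -0.67 was called (adjusted p = 0.0415, and adjusted p = 0.625 with an estimated correlation), with -0.69 on slide 1 and -0.66 on slide 2. The call ended without control 3 (adjusted p = 0.0870), without furan 1 (0.0877), without control 2 and furan 1 together (0.0809) and with normexp (0.214), in a range over all alternatives from 0.00887 to 0.625. Scd, the stearoyl-CoA desaturase, fell by 3.47 (11.1-fold, adjusted p = 0.00281) and Thrsp by 1.55, with a low control 1 (1.61 against 2.59 to 2.78), while the elongase Elovl6 rose by 1.92 (1.14 with normexp). Bile acid metabolism was not called (21 tested, 4 rose and 11 fell, the same adjusted over the list alone, median -0.73, adjusted p = 0.0611). It was called with quantile normalization (adjusted p = 0.0431), with a signal above background on all 8 arrays (0.0211), with the mean of probes (0.0498), with a variance trend (0.0416), without control 3 (0.0486) or furan 3 (0.0227) and on slide 1 alone (0.0114), in a range over all alternatives up to 0.615. In it the uptake transporter Slco1a1 fell by 1.57 and Slc27a5, which links bile acids to CoA, by 1.68, and the export transporter Abcc3 rose by 3.53 (11.5-fold, adjusted p = 0.000101; log2 change 1.02 with normexp). Fatty acid oxidation was not called (25 tested, 2 rose and 3 fell, 1 and 0 adjusted over the list alone, median -0.24, adjusted p = 0.190), but was called without furan 3 (-0.35, adjusted p = 0.0476) and on slide 1 alone (-0.65, adjusted p = 0.00106; over all alternatives up to 0.874), with Acot1, a thioesterase, higher by 4.40. None of 27 tested genes of oxidative phosphorylation passed the threshold in limma, with or without adjustment over the list alone (4 at an unadjusted p below 0.05, median 0.04, camera adjusted p = 0.583, fry adjusted p = 0.783), though the list was called higher with normexp (0.09, adjusted p = 0.0470) and on slide 2 alone (0.20, adjusted p = 0.0378; over all alternatives up to 0.936).

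**Figure D3:**
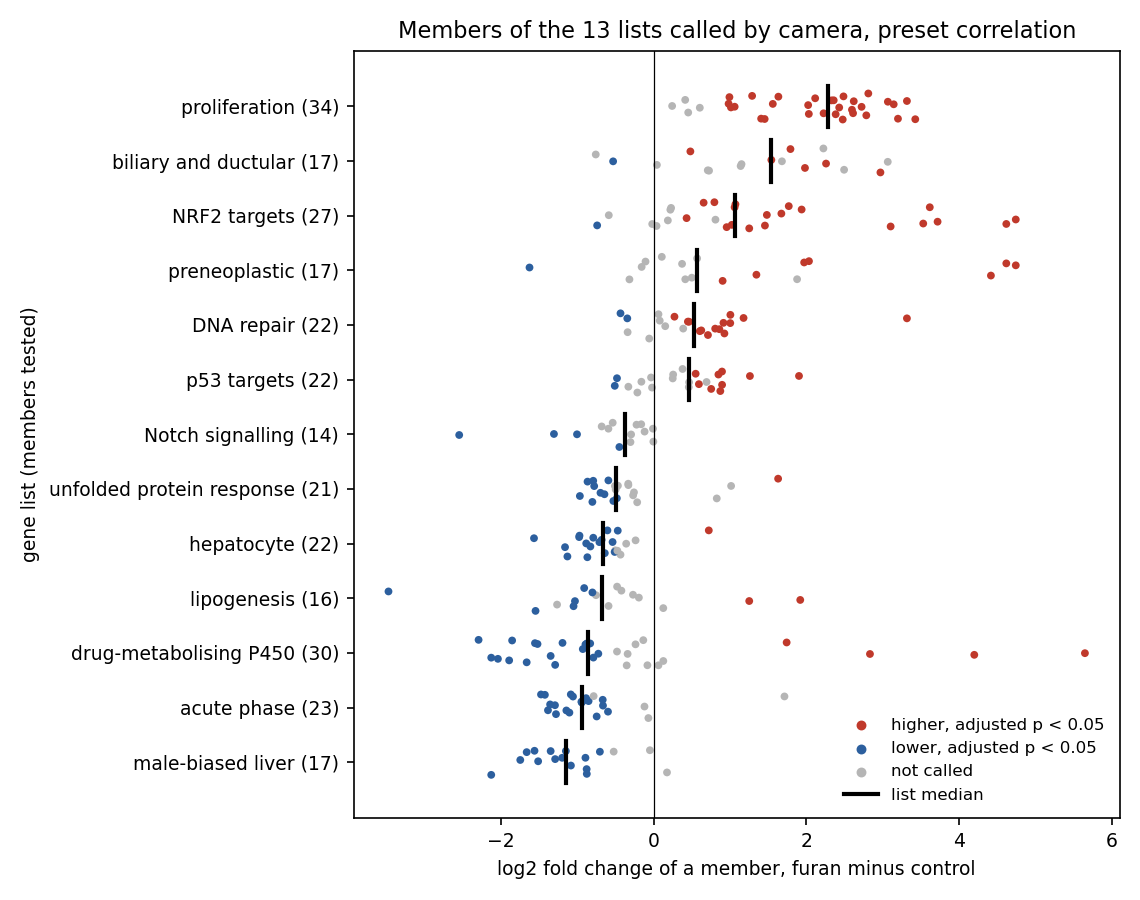
Log2 fold change (furan minus control, x axis) of each tested member of the 13 called gene lists (y axis), in red where the member rose, blue where it fell and grey where it was not called, with a black bar at the list median. Proliferation has a median of 2.28 and male-biased liver one of -1.15.

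Of 17 tested biliary and ductular markers, 6 rose, 1 fell and 10 were not called (8 and 1 adjusted over the list alone). The median of 1.54 was called (adjusted p = 0.0312, and adjusted p = 0.696 with an estimated correlation), with 1.73 on slide 1, 1.16 on slide 2 and 0.67 with normexp. The call ended without control 1 (adjusted p = 0.0565), control 4 (0.0624), furan 1 (0.0879) or furan 2 (0.0587), and with fry (0.218), in a range over all alternatives from 0.000735 to 0.696. Array medians of the list were -0.78, 1.71, -0.40 and -0.23 in controls 1 to 4 and 2.65, 1.92, 0.66 and 0.46 in furan livers 1 to 4, so control 2 was above furan 3 and 4. Cd24 rose by 2.97, though not past the threshold without control 3 (adjusted p = 0.0532), control 4 (0.0517) or furan 2 (0.0601), in a range over all alternatives from 0.00377 to 0.138. Krt19, the cholangiocyte keratin (chromosome 10 from 89081437 to 89081496), had levels of -2.76 ± 2.10 and -2.04 ± 2.03 (SD, n = 4 each), a log2 change of 0.72 ± 1.24 SE that was not called (adjusted p = 0.684) and was -0.19 without furan 1. Intestinal and mucin markers were not called (6 tested, 1 at an unadjusted p below 0.05 and none past limma's threshold, also when adjusted over the list alone, median 1.42, adjusted p = 0.190, fry adjusted p = 0.218), with 2.54 on control 2 and 3.40 on furan 1. The list was called without control 2 (median 2.51, adjusted p = 0.0464), without control 2 and furan 1 (1.85, adjusted p = 0.0162) and on slide 2 alone (1.86, adjusted p = 0.0154), in a range over all alternatives from 0.0154 to 0.696.

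Other cell types gave no called list. Of 24 stellate cell and matrix genes none rose and 2 fell (0 and 1 adjusted over the list alone), with a median of 0.30 that was 0.94 on slide 1 and -0.36 on slide 2 (adjusted p = 0.573), where it was called in opposite directions (adjusted p = 0.0252 and 0.0225 with 1 slide alone; over all alternatives up to 0.994). Fibronectin, Fn1, fell by 0.65. Macrophage genes had a median of -0.14, a mean of 0.10 and a test direction of down (18 tested, 1 rose and 1 fell, none adjusted over the list alone, adjusted p = 0.583). Lymphocyte genes had a median of -0.21 (15 tested, none rose and 1 fell, 0 over the list alone, adjusted p = 0.304), and were called without control 1 (-0.52, adjusted p = 0.00163), with normexp (-0.40, adjusted p = 0.0275) and on slide 2 alone (-0.59, adjusted p = 0.000488, against 0.07 and 0.898 on slide 1, the range over all alternatives). None of 13 endothelial genes was called by limma, also when adjusted over the list alone (1 at an unadjusted p below 0.05, median -0.15, adjusted p = 0.550, fry adjusted p = 0.663). That list was called without control 1 (-0.72, adjusted p = 0.000335) and on slide 2 alone (-0.55, adjusted p = 0.00130, against a median of 0.19 on slide 1; over all alternatives up to 0.880). None of 8 MHC class II genes was called by limma, also when adjusted over the list alone (0 at an unadjusted p below 0.05, median 0.36, adjusted p = 0.190, fry adjusted p = 0.391). They were called as a list without furan 4 (0.65, adjusted p = 0.0244) and on slide 1 alone (1.06, adjusted p = 0.000745, against a median of -0.25 on slide 2; over all alternatives up to 0.839). Erythroid genes had a median of -0.54, with 1 of 8 lower (also adjusted over the list alone, adjusted p = 0.170).

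**Figure D4:**
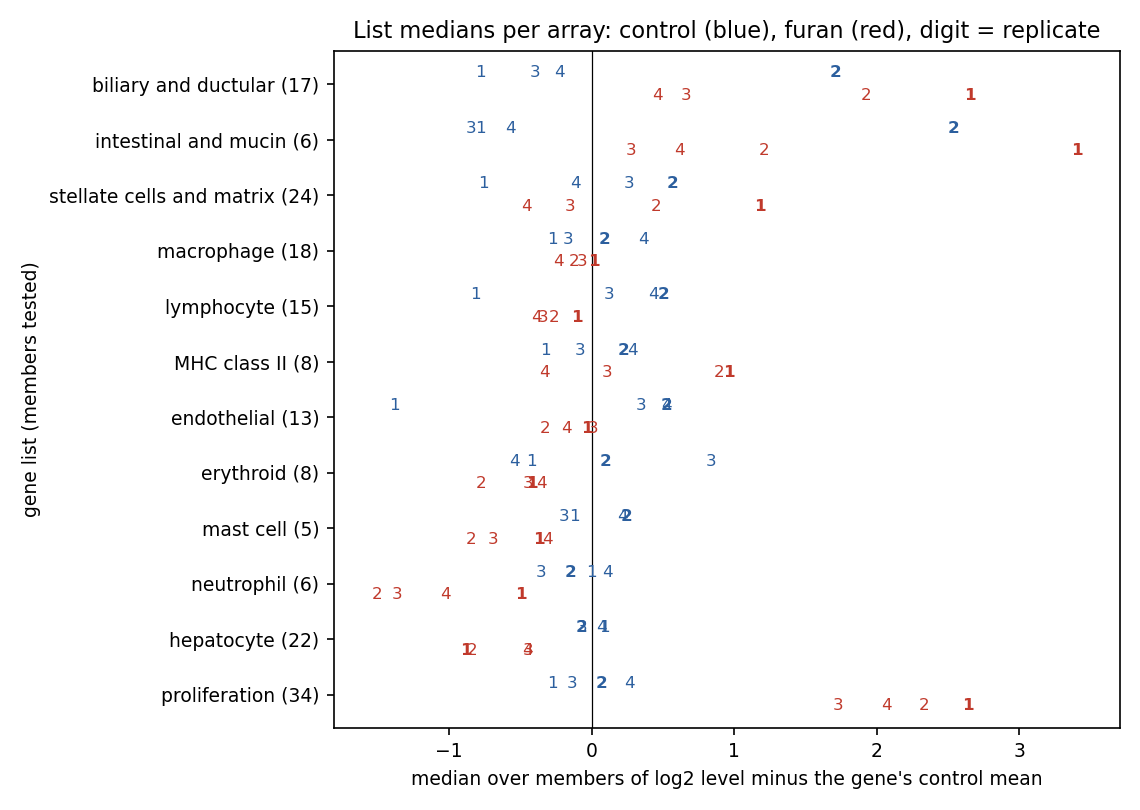
Median over the members of 12 gene lists (y axis) of the log2 level minus the gene's control mean (x axis) on each control array (blue) and furan array (red), with digits for the replicate and control 2 and furan 1 in bold. The biliary list has 1.71 on control 2 and 2.65 on furan 1, while the proliferation list stays between 1.73 and 2.64 in the furan livers.

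Notch signalling was called lower (14 tested, 4 fell, none rose and 10 were not called, the same adjusted over the list alone; median -0.38, adjusted p = 0.0313). It had adjusted p = 0.412 with an estimated correlation, and medians of -0.38 on slide 1 and -0.36 on slide 2. The call ended without furan 4 (adjusted p = 0.0513) and without a filter on dim probes (0.0640), in a range over all alternatives from 0.00248 to 0.412. The receptor Notch1 fell by 2.55 (1.49 as the mean of its probes) and the ligand Dll1 by 1.00 (0.66 with normexp).

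None of the 13 called lists stayed called by camera with an estimated correlation (4 of 35 lists at an unadjusted p below 0.05), and fry called 5 lists up and 12 down. With the slide as a block the same 13 lists were called, with adjusted p from 1.62e-15 to 0.0181, and periportal genes were called lower as well (0.0321).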

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

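For the 3 patterns weighed here, the tests of a shared slide, of a lower share of hepatocytes, of array scaling, of the female pattern and of different tissue pieces were chosen only after the result was seen. The tests of another tissue, of noise in single spots and of brighter arrays were written down before it was seen.

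In 10 of the 268 groups of 4 arrays examined (3.73%), 1 array lay so far from the other 3 that its gap to the nearest of them took up most of the group's range. Chance alone marks about 1 in 20 groups. Control 1 was low for Thrsp, at 1.61 against 2.59 to 2.78 in the other controls. Control 2 was high for Cd24, at 0.0171 against -3.0 to -2.82, and for Gpx2, at 2.16 against -2.42 to -1.92. Control 3 was low for Aldh1a7, at -8.70 against -8.35 to -8.29, though this gene was well above background on no control array. Control 4 was high for Rrm2, at -1.19 against -3.37 to -3.01. Furan 1 was high for Abcc3, at -3.02 against -3.50 to -3.43 in the other furan arrays, and for the median coefficient of variation between replicate spots, at 12.8% against 4.20% to 4.45%. Furan 2 was low for Birc2, at -0.34 against -0.09 to -0.05, and for Socs3, at -4.17 against -3.63 to -3.56. Furan 4 was low for Dbp, at 1.80 against 2.66 to 2.74.

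Control 2 and furan 1 shared high levels of biliary and intestinal markers, with list medians 2.28 and 3.38 above the other 3 controls for control 2, and 1.48 and 2.64 above the other 3 furan arrays for furan 1. Noise of single spots is argued against, since the deviations of both arrays correlated at 0.49 across 10765 probes (genes are not independent replicates) when taken over different spots of each probe. A shared slide stays open, since the same 23 markers lay 1.59 above slide 2 in furan 2 but at -0.25 in control 1, the other arrays of slide 1. Another tissue in the sampled piece may be the source: 2 of the 6 added lists, adipose and mesothelium, lay in the upper 2.5% of random lists matched on brightness in both arrays, although 5 of 6 adipose and 4 of 5 mesothelium genes were well above background on the other 6 arrays too, and the liver's own stellate cell and matrix (0.76 and 1.19), macrophage (0.12 and 0.23) and MHC class II (0.30 and 0.70) lists lay there as well, so the source need not lie outside the liver. A difference between the animals themselves was not tested and stays open.

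Hepatocyte and male-biased genes fell together, with list medians of -0.66 and -1.15. A lower share of hepatocytes stays open. A share lost evenly to all other cell types would raise their markers, but the mean score of macrophage, lymphocyte and endothelial markers changed by -0.0885 (two-sided exact permutation p = 0.857, control SD 0.63, furan arrays between -0.24 and 0.15, -0.39 without control 1 and at most 0.0548 without any other array, 0.23 on slide 1 and -0.40 on slide 2). A gain of biliary cells alone need not raise that score, so it cannot decide. The biliary score changed by 1.35 (exact permutation p = 0.171). On furan arrays 1 to 4 it was 2.64, 1.88, 0.49 and 0.39, beside hepatocyte scores of -0.85, -0.91, -0.45 and -0.45. Control 2 went the other way, with a biliary score of 1.73 and a hepatocyte score of -0.06. A scaling constant per array moves all genes alike. The hepatocyte median relative to all genes cannot show its effect (-0.63 in the main result and with median centring). Array scaling that depends on level is argued against, since that median was -0.50 with quantile normalization (camera's preset correlation, adjusted p = 0.0238). With normexp, a background correction, it was -0.46, with the list still called at the preset correlation (adjusted p = 0.00312). In the main result the hepatocyte list had adjusted p = 0.512 with an estimated correlation. A shift towards the female pattern stays open, since female-biased genes moved both ways: 4 of 9 fell (Cux2, Cyp2a1, Cyp2c7 and Cyp3a9), 2 rose (Cyp2c12 and Prlr), and their median of -0.66 lies within the members' spread (SD 2.14). A lower output of these genes in hepatocytes exposed to furan stays open too, as a hypothesis that these data could not test.

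The proliferation list rose on every furan array. Brighter furan arrays and the handling of background are argued against, since with normexp the list median of 0.85 stood at percentile 100 of 10000 random lists matched on level, whose median was -0.25, and 25 of 34 genes still rose. Different tissue pieces stay open. Without control 2 and furan 1 the proliferation median was 2.13, 30 genes rose and the list was called at camera's preset correlation (in the main result adjusted p = 0.321 with an estimated correlation). The biliary median was still 1.43 without them, so leaving them out cannot decide. Control 2, with a biliary median of 1.71, had a proliferation median of 0.07. Furan 3 and 4 had biliary medians of 0.66 and 0.46 beside proliferation medians of 1.73 and 2.07. A larger number of dividing cells may be the source, and which cell type divides was not tested.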

How the results depend on the processing

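The alternatives without control 2 and furan 1, with each slide alone and with outlier spots kept were chosen after seeing the data, and all others were fixed beforehand. Signal over background limits the dim genes: among the dimmest of 4 equal groups of features the median log2 change was -0.08 in the main result and -0.40 with normexp, and 2708 against 517 features were called lower, while the brightest group had 0.01 and 0.04. Of the 125 called genes taken from the rule, 99 stayed called in the same direction in every alternative of scaling, background, filter, probes, block or variance that was fixed beforehand and kept all 8 arrays (only 110 of the 125 pass the filter on all 8 arrays and were tested there). In every fit that left out 1 array 99 stayed called, and 94 in both. These counts leave out the stricter tests: 92 of the 125 had an adjusted p below 0.01, and single genes were not counted with treat. With each slide alone (2 against 2 arrays) 40 stayed called on both. Normexp moved the log2 change of 28 of the 125 by over 1.5 times and ended or turned 7 calls. Of the 13 called lists, 10 stayed called whichever array was left out and 13 on each slide alone, but 0 of the 35 lists were called by camera with an estimated correlation (4 at an unadjusted p below 0.05; fry called 5 up and 12 down). The replicate numbers shared by the groups did not pair the arrays (correlations of same-numbered deviations of -0.30, 0.12, 0.28 and 0.04), and with the replicate number as a block 2380 genes were higher and 2171 lower.

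Genes higher numbered 1881 with median centring, 300 on slide 1, 845 on slide 2, 1647 at an adjusted p below 0.01 and 435 with treat against 1.5-fold. Genes lower numbered 6007 with normexp, 1916 with median centring, 194 on slide 1, 611 on slide 2, 1361 at an adjusted p below 0.01 and 197 with treat. Genes at least 2-fold higher numbered 343 with normexp and 300 on slide 1, and those at least 2-fold lower 427 with normexp, 194 on slide 1 and 399 on slide 2. By construction, a slide alone has fewer arrays, a smaller threshold passes fewer genes, and the offset of normexp shrinks the folds of dim signals, so that fewer reach 2-fold. For the 6007 lower calls with normexp and for median centring the cause was not tested. Lists up numbered 0 and lists down 0 with an estimated correlation. The estimate was above the preset 0.01 for every called list but p53 targets (-0.0077), from 0.0149 for DNA repair to 0.68 for male-biased liver. A higher correlation between members makes the mean of a list less certain, so adjusted p values at the preset can be too small. Camera's unadjusted p also rose where the estimate was below or near the preset. It went from 0.00449 to 0.0204 for p53 targets and from 5.87e-05 to 0.00839 for DNA repair. A higher correlation alone therefore does not account for the lost calls, and what else raised these p values was not tested. Lists down numbered 12 on slide 1, 12 on slide 2 and 12 with fry, which does not compare a list with other genes.

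Leaving out each array in turn gave 2237 to 3013 genes higher and 1932 to 3006 lower, the lowest without furan 2 (1932). It gave 761 to 1012 at least 2-fold higher, 516 to 768 at least 2-fold lower, 5 to 7 lists up and 7 to 11 lists down, the highest without furan 3 (11). The cause was not tested.

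Directions turned in 10 cases for 9 results. With normexp, Bcl2l11 had -0.0768, Cd86 -0.0587, Eda2r -0.28 and Uhrf1 -0.36 (adjusted p = 0.0243; over its alternatives from 0.00619 to 0.208). The dimmest group of features had a median of -0.40 with normexp, so a negative sign there cannot decide the direction of a dim gene. On slide 2, Cd86 had -0.00894, Cyp2e1 0.0642 and the stellate cell and matrix list a median of -0.36 (0.94 on slide 1, both called). Lists called in neither fit are not counted here: on 1 slide their medians also changed sign for MHC class II (-0.25), cholesterol synthesis (0.27) and imprinted genes (-0.03) on slide 2, and for macrophage (0.13), lymphocyte (0.07), endothelial (0.19), heat shock (-0.00118) and oxidative phosphorylation (-0.11) genes on slide 1, and for the apoptosis list (-0.08 on slide 2). With all 8 arrays, medians of such lists also crossed 0 for iron metabolism with quantile normalization (0.02, against -0.34), for apoptosis with normexp (-0.15, the lowest), quantile normalization, median centring, array weights and outlier spots kept, for cholesterol synthesis with normexp (0.00451) and array weights (0.02), for chromatin modifiers with normexp (-0.06), no filter (-0.00187) and the 8-array filter (-0.00187) and for heat shock with the mean of probes (-0.01). Leaving out 1 array also turned list medians, for macrophage (up to 0.02) and cholesterol synthesis (up to 0.16). It did so for stellate cells and matrix (down to -0.04), imprinted genes (-0.02), heat shock (-0.06), apoptosis (-0.05) and oxidative phosphorylation (-0.06). Cdkn1a had 0.11 as the mean of its probes, which differ in sign, Fabp1 0.13 with quantile normalization and Krt19 -0.19 without furan 1 (-0.19 to 1.75 over the arrays left out, the highest without control 2). The cause was not tested for slide 2, Fabp1, Krt19 and the lists with an array left out.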

Other observations

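The tests below on splits of the arrays were chosen only after the result was seen; the gene lists were fixed beforehand, apart from the 7 added ones.

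Clock genes moved in both directions and the circadian list was not called (14 tested, 4 rose, 5 fell and 5 did not pass, with 4 and 6 adjusted over the list alone, median -0.25, adjusted p = 0.462). Npas2, an activator of the clock, fell by 2.15 on the log2 scale (1.39 as the mean of its probes), Nfil3 by 1.09 and Bhlhe40 by 1.08, both repressors of clock targets, and Dbp, an output gene of the clock, rose by 1.92 (furan 4 at 1.80, the other furan arrays at 2.66 to 2.74). Hours of death per animal were not given in the sources used here. Iron genes were not called as a list by camera (18 tested, 1 rose, 8 fell, 2 and 8 adjusted over the list alone, median -0.34, adjusted p = 0.143), while fry gave an adjusted p = 0.00641 (over all alternatives from 0.00641 to 0.567) and the median was 0.02 with quantile normalization. Hamp fell by 1.42, Tfr2, a sensor of iron in hepatocytes, by 1.24 and the ferroxidase Cp by 0.95, and the transferrin receptor Tfrc rose by 0.82.

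Chromatin modifiers were not called (52 tested, 7 rose, 5 fell, 4 and 5 adjusted over the list alone, median 0.07, adjusted p = 0.574). The lysine methyltransferase Smyd2 rose by 0.83. Setd7, with 1.80 in the main result, had 0.12 with normexp (adjusted p = 0.440, the highest of its alternatives, against 0.00125 as the lowest). Uhrf1, which guides maintenance of DNA methylation, had 1.33 in the main result and -0.36 with normexp, and its call ended without control 2 (adjusted p = 0.0514) or furan 2 (0.0535), in a range over its alternatives from 0.00619 to 0.208. Imprinted genes were not called as a list (18 tested, 2 rose, 2 fell, the same adjusted over the list alone, median 0.18, adjusted p = 0.583), but held H19, higher by 4.42, and Phlda2, higher by 1.78, beside Igf2, which fell by 1.63, and Mkrn3, which fell by 0.72. Apoptosis genes split evenly (29 tested, 7 rose, 7 fell, the same adjusted over the list alone, median 0.01, adjusted p = 0.825), with Bak1, which opens the mitochondrial membrane, higher by 1.56 and Bmf lower by 1.69 on the log2 scale. Of 14 heat shock genes 4 rose and 3 fell (4 and 4 adjusted over the list alone, median 0.03, adjusted p = 0.703), with the small chaperones Hspb1 and Cryab higher by 1.84 and 1.61. Of 22 genes of cholesterol synthesis 2 rose and 4 fell (the same adjusted over the list alone, median -0.02, adjusted p = 0.591, called on slide 1 alone with a median of -0.41 and adjusted p = 0.0252, against 0.27 and 0.165 on slide 2; over all alternatives up to 0.882), among them Sc5d, which fell by 0.93. Among mast cell genes 2 of 5 fell (1 rose and 2 fell adjusted over the list alone, median -0.49, adjusted p = 0.170): the proteases Mcpt10 by 1.27 and Mcpt9 by 1.08. Fry called the mast cell list (adjusted p = 0.00821; over all alternatives up to 0.615). Among neutrophil genes 2 of 6 fell (4 adjusted over the list alone, median -0.87, adjusted p = 0.0875), and the list was called without furan 1 (-1.10, adjusted p = 0.0427), without control 2 and furan 1 (-1.02, 0.0162), with median centring (0.0339), without a filter on dim probes (0.0396), with the replicate number as a block (0.0158), on slide 2 alone (0.00234) and with fry (0.0319; over all alternatives from 0.00234 to 0.512).

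Of the 35 splits of the 8 arrays into 4 and 4, only 1, the real one, gave as many called genes (6033, against 0 as the highest of the other splits). The same held for genes with at least a 2-fold change (1585, against 0). Each count has an exact permutation p = 0.0286, the smallest that 35 splits can give. Every other split mixes furan and control livers, so their difference adds to the spread within groups and lowers the calls. The 0 there does not by itself exclude chance. For the 13 called lists 15 of the 35 splits gave as many, with 19 as the highest of the others, so chance cannot be excluded for that count. The split of slide 1 against slide 2 gave 14 lists and 0 genes by limma (1252 features at an unadjusted p below 0.05). With the slide as a block, the real comparison gave 6 lists up and 8 down. No gene had a called interaction of slide and treatment (0 by limma, 1111 at an unadjusted p below 0.05), and 4030 of the 6033 called features (66.8%) changed more on slide 1.

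For single lists the mean change of the members was set against the same splits by an exact permutation test. The real split had the largest absolute mean for 15 of 35 lists, each with an exact permutation p = 0.0286, the smallest that 35 splits can give (0.0667 after Benjamini-Hochberg adjustment over 35 lists). Proliferation, DNA repair, NRF2 targets, p53 targets, hepatocyte, male-biased liver, acute phase, lipogenesis, unfolded protein response and Notch signalling were among them. So were the pericentral, periportal, bile acid metabolism, circadian clock and iron metabolism lists, which camera did not call. The test thus did not separate called from uncalled lists. Preneoplastic genes (exact permutation p = 0.0857), drug-metabolising P450 (0.114) and biliary markers (0.171) were not.

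Deviations of control 2 and furan 1 from the other 3 arrays of their group are given here as list medians with the percentile among random lists. They were 0.55 (100) and 0.17 (91.25) for smooth muscle, 1.31 (100) and 0.50 (99.01) for adipose, 0.04 (57.91) and 0.37 (96.35) for enterocyte genes. They were 0.21 (75.4) and 0.96 (98.79) for enteroendocrine, 0.25 (58.46) and 0.20 (33.39) for pancreas acinar, 1.6 (99.96) and 1.83 (100) for mesothelium and -0.28 (0.16) and -0.24 (14.8) for female-biased liver genes. Lists of cells resident in the liver also lay in the upper 2.5% in both arrays: stellate cells and matrix at 0.76 (100) and 1.19 (100), macrophage at 0.12 (99.91) and 0.23 (100), and MHC class II at 0.30 (99.84) and 0.70 (99.99). In control 2 alone so did lymphocyte genes at 0.67 (99.84; 0.31 in furan 1) and endothelial genes at 0.70 (100; 0.14 in furan 1), and in furan 1 alone neutrophil genes at 0.92 (99.86; -0.20 in control 2). The mesothelial gene Msln deviated by 1.79 and 1.83, Wt1 by 1.68 and 1.52, and the adipose gene Lpl by 1.80 and 1.86.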
